A study of Homo sapiens with 8 samples.

How the data were processed

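RNA sequencing libraries of MEL1, a human embryonic stem cell (ESC) line, were analysed from their deposited gene tables. There were 8 libraries in 4 groups of 2. Per the labels, cells were exposed at the ESC stage to TCDD, a dioxin that binds the aryl hydrocarbon receptor (AHR), at 2 nM in DMSO, or to DMSO alone. Libraries were taken at D1, just before differentiation, and at D2, which per the labels followed 2 days of cardiac differentiation in a medium with 5 µM of a GSK3 inhibitor. The length of the exposure, and whether replicates came from separate cultures, are not given in the sources used here. The p-values therefore measure only the spread between these samples, which may be technical.

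Each table held the authors' raw read count per gene symbol, with no normalisation, as the whole-number values show. Reads had been trimmed with cutadapt 1.9.1, aligned with STAR and counted with featureCounts 1.5.1 on the hg19 build, per the submitters' processing notes. The STAR version, the annotation, the strand setting and the treatment of reads that match several genes are not given in the sources used here. Counts of overlapping genes, antisense partners and near-identical copies are therefore uncertain. The deposited tables listed 27317 symbols, of which 4199 had no count in any library. Totals ran from 34873055 to 43770420 counts per library. RNR2, a mitochondrial ribosomal RNA, took 0.449% to 0.887% of a library.

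Replicates were compared by a chi-square test of their counts over genes with at least 20 counts. The statistic per gene was 3.86 for DMSO at D1, 3.21 for DMSO at D2, 6.59 for TCDD at D1 and 4.43 for TCDD at D2. These are more than the value of 1 that sampling noise gives, and each library was treated as a sample. The test cannot tell separate cultures from technical repeats, so it does not show that the libraries are independent. Groups came from the sample titles. Analyses ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Low genes were removed with edgeR's filterByExpr on the groups, which left 17268 genes. Libraries were scaled by TMM factors (0.958 to 1.04), and levels are given as counts relative to the scaled library totals (edgeR's CPM). All 8 libraries entered a single edgeR quasi-likelihood fit with a mean per group (common biological coefficient of variation 3.86%), and F tests were two-sided with Benjamini-Hochberg adjustment over all genes tested. Genes past an adjusted p of 0.05 were called changed. The 5 comparisons were TCDD against DMSO at D1 and at D2, D2 against D1 with DMSO and with TCDD, and the TCDD effect at D2 minus that at D1. CPM values are means ± SD over 2 libraries, and log2 fold changes carry standard errors (SE) derived from the F statistic. Such an SE can be too small where a group holds only a few counts.

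Before the data were examined, 38 gene lists, the named-gene rule, the tests and most alternatives were fixed. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 between genes, two-sided, with Benjamini-Hochberg adjustment over 36 lists. The same lists were tested with the correlation estimated from the data, and with fry. The list of mitochondrially encoded RNA used names with the prefix MT-, matched no symbol and was not tested, although the 2 mitochondrial ribosomal RNAs were counted under their RefSeq names, RNR1 and RNR2. The HOX list had 4 tested members, too few for the test. Counts within a list were also adjusted over the list alone. The rule named the 10 largest rises and the 10 largest falls among called genes with a mean of at least 1 CPM and no overlap between the groups' libraries. For the difference of TCDD effects it took 5 in each direction without the overlap condition, and it took none for D2 against D1 with TCDD. Symbols that begin with LOC, MIR, SNOR, SNHG, LINC or RN7, contain -AS or are open reading frame names were passed over, which left in the long non-coding genes PEG13 and HOTAIRM1. A set of 20 AHR, pluripotency, mesoderm, cardiac and housekeeping genes was always included, as were up to 4 members with the smallest p of each list that passed or had at least 3 called members. Results for some genes that the rule names are not reported. Any other gene named was chosen after its values were seen, namely the listed members of small counts and of the paragraphs on further gene groups. Among the always-named genes, HAND1 and NKX2-5 were too low to test, with at most 6 and 3 counts in a library.

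A fold against a group with no count was computed against a floor of 3 counts over the group, and a ratio against 1 to 3 counts is given with an exact 95% interval. Both cover counting error only. The overlap of the D1 and D2 calls used a one-sided Fisher exact test. The correlation between the TCDD effect at D2 and the differentiation effect used log2 CPM with a prior count of 2. Because both effects contain the DMSO libraries of D2, it was set beside 100 simulations with no TCDD effect and beside versions that share no library. Chromosome order, GC content and transcript length came from GRCh38 annotation, since hg19 annotation was not used here, and no coordinates are given. Of the symbols, 24909 matched as current names, 1293 through a synonym and 1115 did not match. GC content and length were known for 16574 tested genes (96%).

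The fit was tested on simulated counts, with 50 genes changed at each of 4 fold sizes. They were drawn from each gene's mean over all 8 libraries, its fitted dispersion and the library totals. The changed genes had a mean of at least 1 CPM, with equal numbers raised and lowered, and all others were level across groups. The shares below therefore do not cover low genes, and need not hold for D2 against D1, where most genes changed in the data. At D1 (17018 genes tested) the fit recovered 66% of genes changed 1.25-fold, 84% at 1.5-fold and 100% at 2-fold and at 4-fold. At D2 (17046 genes) the shares were 60%, 78%, 100% and 100%. For D2 against D1 with DMSO (17034 genes) they were 74%, 86%, 100% and 100%, and with TCDD (17038 genes) 60%, 84%, 98% and 100%. For the difference of TCDD effects (17030 genes) they were 38%, 68%, 98% and 100%. False calls beside true calls numbered 12 and 175 at D1, 21 and 169 at D2, 24 and 180 for D2 against D1 with DMSO, 16 and 171 with TCDD, and 13 and 152 for the difference. The share of false calls was thus above the nominal 5% in these runs. Of 100 random lists, camera gave an unadjusted p under 0.05 to 1, 0, 0, 0 and 1 in the same order. The simulated genes were drawn independently, so these lists cannot show how camera behaves where members vary together.

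The alternatives were RLE size factors, no composition scaling, the DESeq2 Wald test, limma-voom, no filter beyond 1 count, a mean of at least 1 CPM, the replicate number as a block, a fit on only the groups compared, a further threshold of 1 on the absolute log2 fold change, and leaving out each library in turn. Where that left 1 library in a group, it was assumed to vary like the other groups. A replicate block within each time and a block with numbers crossed between D1 and D2 were added after seeing the data.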

Results

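Transcript levels were measured in MEL1 human embryonic stem cells by RNA sequencing. Cells had been exposed at the ESC stage to 2 nM TCDD, a dioxin and high-affinity ligand of the aryl hydrocarbon receptor (AHR), or to its solvent DMSO. They were sampled at D1, just before differentiation, or at D2, after 2 days of cardiac differentiation under a GSK3 inhibitor, which activates Wnt signalling and drives cells towards mesoderm. Each of the 4 groups had 2 libraries, with 34873055 to 43770420 counts each. The study asked which genes TCDD changed in ESCs and in early mesoderm. Unless another test is named, adjusted p-values are Benjamini-Hochberg values of the edgeR quasi-likelihood F test over 17268 genes.

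In undifferentiated cells at D1, TCDD raised 8 of 18 AHR target genes. CYP1A1, a cytochrome P450 that metabolises aromatic hydrocarbons, rose 113-fold, from 0.787 ± 0.0373 CPM with DMSO to 89.4 ± 16.5 CPM with TCDD (SD, n = 2 each), a log2 fold change of 6.82 ± 0.21 (SE, edgeR adjusted p = 1.48e-06). TIPARP, an ADP-ribosyltransferase that limits AHR signalling, rose 10.8-fold, from 5.89 ± 0.169 to 63.7 ± 2.53 CPM. CYP1B1, a related P450, rose 5.97-fold, from 7.92 ± 0.13 to 47.3 ± 0.177 CPM, and AHRR, the AHR repressor, rose 2.28-fold to 3.54 ± 0.252 CPM. LRAT, the enzyme that esterifies retinol for storage, rose 27.2-fold, from 23.2 ± 1.81 to 631 ± 1.04 CPM (edgeR adjusted p = 3.68e-18). AHR itself stood at 12.7 ± 1.3 CPM with TCDD and 15.6 ± 0.512 CPM with DMSO (edgeR adjusted p = 0.187), and its partner ARNT at 70.3 ± 2.17 and 70.5 ± 1.83 CPM (edgeR adjusted p = 0.993).

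**Figure D1:**
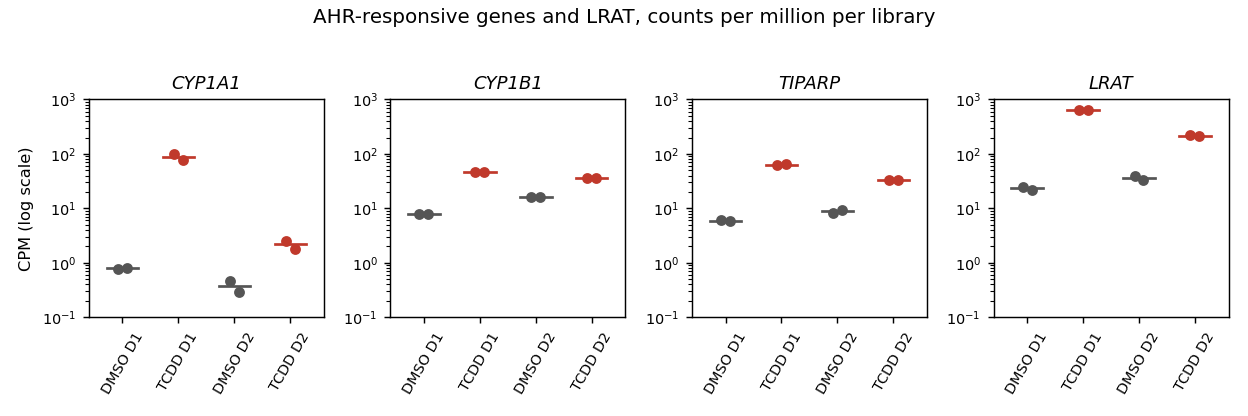
CPM on a log scale (vertical axis) of CYP1A1, CYP1B1, TIPARP and LRAT in the 4 groups (horizontal axis). Points are the 2 libraries of a group and lines their mean. TCDD libraries lie above DMSO libraries of the same time in all 4 genes, and CYP1A1 with TCDD was at 89.4 CPM at D1 and 2.19 CPM at D2.

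Across the transcriptome at D1, 197 of 17268 genes changed, 127 higher and 70 lower, of which 26 and 3 by at least 2-fold. The split depended on single libraries, with 90 higher and 156 lower without TCDD replicate 1 of D1 and 66 and 12 without DMSO replicate 1 of D1, and was 229 and 251 with no filter beyond 1 count. The other largest rises were MYADML2 (7.00-fold), the homeobox gene SIX6 (6.24-fold), APELA (5.86-fold), which encodes an early-embryo ligand of the apelin receptor, LHX4 (4.35-fold), the protocadherin PCDH8 (3.94-fold) and the dynein gene DNAH5 (3.80-fold). Falls were smaller. LEFTY1, an inhibitor of Nodal signalling, fell by 1.33 ± 0.23 on the log2 scale, from 5.51 ± 2 to 2.2 ± 0.0294 CPM (edgeR adjusted p = 0.0211), and its paralog LEFTY2 fell by 0.62. GRPR, a receptor for gastrin-releasing peptide, fell by 0.88, PEG13 by 0.78, PROX1 by 0.73, the BMP target ID1 by 0.68, ST6GAL2 by 0.68, VGLL3 by 0.51, CNKSR2 by 0.51 and SLC24A2 by 0.47. Pluripotency regulators were near their DMSO level, with log2 fold changes of -0.00 ± 0.05 for POU5F1, -0.10 ± 0.07 for NANOG and -0.16 ± 0.05 for SOX2 (edgeR adjusted p = 0.993, 0.687 and 0.187). The reference transcripts ACTB and GAPDH had log2 changes of 0.08 ± 0.04 and 0.14 ± 0.04 (edgeR adjusted p = 0.488 and 0.154).

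Of 36 gene lists tested at D1, 7 passed camera, 4 in the upward and 3 in the downward direction. Of 18 AHR target genes, 8 rose, 1 fell and 9 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 8.53e-83, and adjusted p = 0.00306 with an estimated correlation). Besides the genes above, NQO1, a quinone reductase, rose 1.22-fold, and ID1 was the member that fell. Of 30 glycolysis and hypoxia genes, 8 rose and 22 did not pass, and 18 rose when adjusted over the list alone (camera adjusted p = 5.31e-17, and adjusted p = 0.486 with an estimated correlation). Examples were BNIP3 (log2 fold change 0.31), a mitophagy receptor, LDHA (0.24), lactate dehydrogenase, P4HA1 (0.26), a collagen prolyl hydroxylase, and ADM (0.45), adrenomedullin. Of 17 Nodal and Activin targets, 1 rose and 3 fell, 2 and 6 adjusted over the list alone (camera adjusted p = 0.0127, and adjusted p = 0.584 with an estimated correlation). The falls were LEFTY1, LEFTY2 and SKIL (-0.25), and SMAD7, an inhibitory SMAD, rose (0.50). Of 20 BMP and SMAD targets, 1 rose and 3 fell, 1 and 4 adjusted over the list alone (camera adjusted p = 0.0174, and adjusted p = 0.486 with an estimated correlation), with BMP4 lower (-0.41). Of 32 pluripotency genes, 2 rose and 4 fell, 3 and 8 adjusted over the list alone (camera adjusted p = 0.0211, and adjusted p = 0.62 with an estimated correlation). PRDM14 was lower (-0.28), and the neuropeptide galanin, GAL (0.38), and the Wnt antagonist SFRP2 (0.27) were higher. Of 23 unfolded protein and amino acid stress genes, 1 rose, DDIT4 (0.37), an inhibitor of mTOR signalling, and 2 adjusted over the list alone (camera adjusted p = 0.0299, and adjusted p = 0.62 with an estimated correlation). Of 11 paraxial mesoderm genes, 1 rose, CYP26A1 (0.54), which degrades retinoic acid, with 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0355, and adjusted p = 0.486 with an estimated correlation). The other 29 lists had camera adjusted p from 0.0636 to 0.819.

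Of the 39 D1 calls named by the rule, 16 held in all 8 fits that left out a library. APELA lost its call without either library of D2 in either treatment (edgeR adjusted p = 0.0977 to 0.0987), LEFTY1 without either D2 library of DMSO or any of the 4 TCDD libraries (0.0805 to 0.106). PROX1, BMP4 and SLC24A2 lost it without any of the 4 D1 libraries (0.0759 to 0.487, 0.0742 to 0.178 and 0.0686 to 0.138), LEFTY2 and VGLL3 without replicate 1 of DMSO or TCDD at D1 (0.148 to 0.479 and 0.0908 to 0.225), and CNKSR2, SKIL and CYP26A1 without either DMSO library or replicate 1 of TCDD at D1 (0.0797 to 0.296, 0.0538 to 0.409 and 0.0627 to 0.103). SFRP2 and SMAD7 lost it without DMSO replicate 2 or TCDD replicate 1 of D1 (0.0897 to 0.157 and 0.0616 to 0.0967), ADM and PRDM14 in 3 fits (0.053 to 0.127 and 0.0803 to 0.146), and P4HA1 without either DMSO library of D1 (0.056 to 0.127). Leaving out replicate 1 of DMSO at D1 ended the calls of BNIP3 (0.0871), LDHA (0.146) and ST6GAL2 (0.0704), and leaving out replicate 2 that of NQO1 (0.106). The count fell from 197 to 78 without replicate 1 of DMSO at D1.

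At D2, TCDD-exposed cells had lower transcript levels of genes that mark the primitive streak, the embryonic source of mesoderm. MIXL1, a streak homeobox factor, was at 128 ± 12.5 CPM with TCDD and 297 ± 15.9 CPM with DMSO (SD, n = 2 each), a log2 fold change of -1.21 ± 0.06 (SE, edgeR adjusted p = 2.13e-10). T, encoding Brachyury, fell from 90.5 ± 3.12 to 48.6 ± 4.76 CPM (log2 fold change -0.90 ± 0.06, edgeR adjusted p = 1.16e-08), and EOMES, a T-box factor required for mesendoderm, from 191 ± 7.44 to 106 ± 6.93 CPM (-0.86 ± 0.05, edgeR adjusted p = 1.29e-09). The early cardiac and endoderm factor GATA4 fell from 11.1 ± 0.227 to 7.4 ± 1.4 CPM (-0.59 ± 0.12, edgeR adjusted p = 0.00414). The mesoderm factors MESP1 and ISL1 did not pass, with MESP1 at 1.32 ± 0.0423 against 1.04 ± 0.0428 CPM and ISL1 at 0.394 ± 0.221 against 0.247 ± 0.0747 CPM (edgeR adjusted p = 0.515 and 0.575). SOX2, a pluripotency and neural factor, rose from 240 ± 8.61 to 361 ± 14.9 CPM (0.59 ± 0.05, edgeR adjusted p = 1.32e-07), while POU5F1 (0.13 ± 0.05) and NANOG (-0.15 ± 0.07) did not pass (edgeR adjusted p = 0.162 and 0.27).

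**Figure D2:**
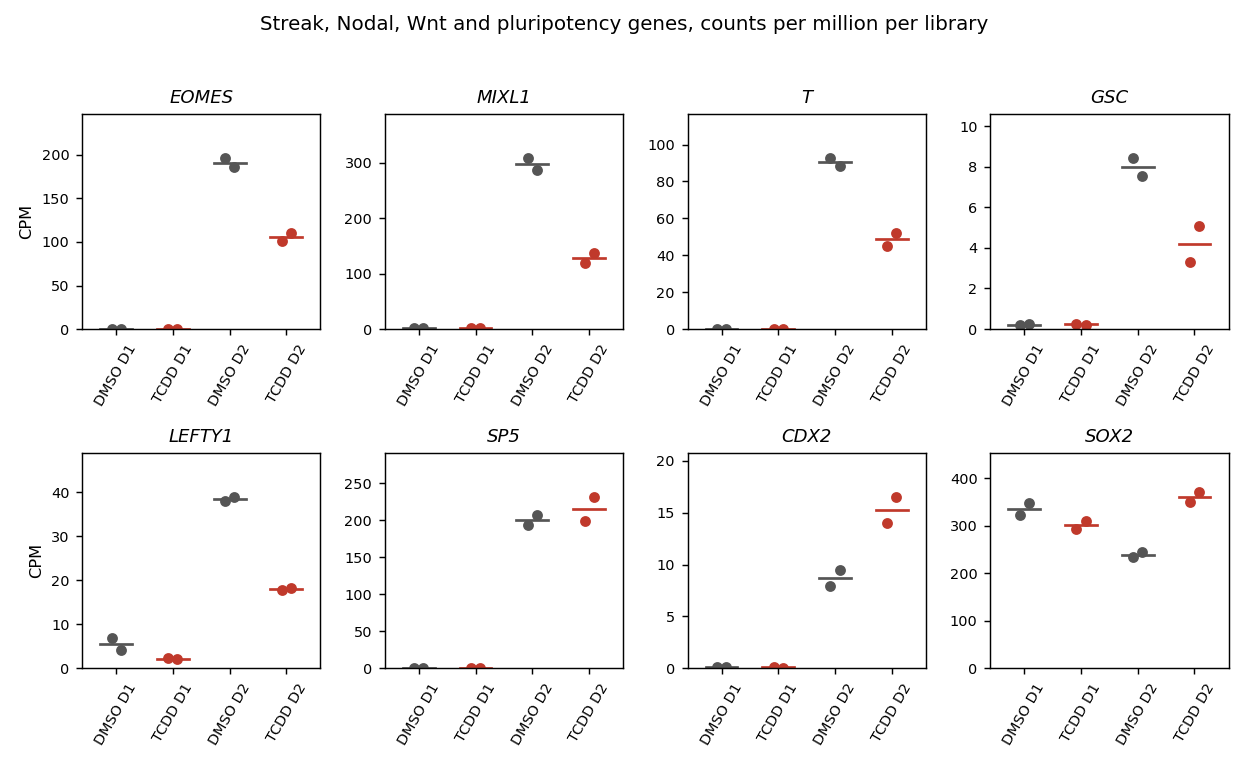
CPM (vertical axis, linear from 0) of EOMES, MIXL1, T, GSC, LEFTY1, SP5, CDX2 and SOX2 in the 4 groups (horizontal axis), with points for the 2 libraries of a group and lines for their mean. At D2, MIXL1 was at 297 CPM with DMSO and 128 CPM with TCDD, CDX2 at 8.69 and 15.3 CPM, and SP5 at 200 and 215 CPM.

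In all, 500 of 17268 genes changed with TCDD at D2, 241 higher and 259 lower, of which 23 and 30 by at least 2-fold. The split was 213 and 319 with no composition scaling, 207 and 157 with DESeq2 and 258 and 249 with RLE size factors. Among the largest falls were ARHGAP40 (log2 fold change -1.38), DKK4 (-1.35) and DKK1 (-1.25), which encode secreted Wnt antagonists, GMPR (-1.33), FGF4 (-1.23), MIXL1, RIT2 (-1.13), ZDHHC8P1 (-1.13) and NPAP1 (-1.11). The largest rises were APELA (6.34-fold), LRAT (5.94-fold), MYADML2 (5.93-fold), CYP1A1 (5.89-fold), SOX21 (5.60-fold), PCDH8 (5.17-fold), the glycosyltransferase GALNT5 (4.70-fold), LHX4 (3.99-fold), TIPARP (3.69-fold) and the adrenergic receptor ADRA2A (2.30-fold). CYP1A1 reached only 2.19 ± 0.529 CPM with TCDD against 0.378 ± 0.122 CPM with DMSO. TIPARP overlaps an antisense gene whose reads cannot be told apart without a stated strand setting, and the near-identical LEFTY1 and LEFTY2 may share reads.

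Of 36 lists tested at D2, 9 passed camera, 4 in the upward and 5 in the downward direction, and 3 of these passed with an estimated correlation. Of 17 Nodal and Activin targets, 1 rose and 8 fell, 2 and 11 adjusted over the list alone (camera adjusted p = 3.51e-28, and adjusted p = 0.024 with an estimated correlation). The Nodal inhibitor LEFTY1 (-1.10) and the growth factor GDF3 (-0.83) were lower, and NODAL itself was at 263 ± 15.3 against 291 ± 16.7 CPM (edgeR adjusted p = 0.239). Of 23 primitive streak genes, 2 rose and 9 fell, 3 and 12 adjusted over the list alone (camera adjusted p = 1.19e-25, and adjusted p = 0.024 with an estimated correlation), among them WNT3 (-0.97), a Wnt ligand needed for streak formation. Of 18 AHR target genes, 6 rose and 1, ID1 (-0.47), fell, 8 and 1 adjusted over the list alone (camera adjusted p = 1.58e-18, and adjusted p = 0.024 with an estimated correlation), with CYP1B1 2.25-fold higher. AHRR was at 1.35 ± 0.122 against 1.19 ± 0.133 CPM and did not pass (edgeR adjusted p = 0.785).

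The other 6 lists that passed at D2 lost the call when the correlation was estimated. Of 20 cardiac and lateral mesoderm genes, 5 fell, also when adjusted over the list alone (camera adjusted p = 0.00991, and adjusted p = 0.199 with an estimated correlation), including GATA6 (-1.53), HAS2 (-0.99), which makes hyaluronan, and APLNR (-0.80), the apelin receptor. GATA6 is absent from the largest falls above because it missed the level or the overlap condition of the rule. Of 20 BMP and SMAD targets, 4 fell, 6 adjusted over the list alone (camera adjusted p = 0.0273, and adjusted p = 0.486 with an estimated correlation), ID1, ID4 (-0.53), BAMBI (-0.34) and BMP4 (-0.34). Of 23 FGF and ERK targets, 1 rose and 1 fell, PHLDA1 (0.25) and FOS (-0.61), 1 and 2 adjusted over the list alone (camera adjusted p = 0.0222, and adjusted p = 0.733 with an estimated correlation). Of 9 trophoblast and amnion genes, 1 rose, CDX2 (0.81), which also marks posterior streak, and 3 adjusted over the list alone (camera adjusted p = 0.00434, and adjusted p = 0.199 with an estimated correlation). Of 24 epithelial genes, 3 rose, also when adjusted over the list alone (camera adjusted p = 0.00468, and adjusted p = 0.486 with an estimated correlation), the integrin ITGB4 (0.35) and the keratins KRT8 (0.19) and KRT19 (0.17). Of 16 Notch genes, 1 rose, the ligand JAG1 (0.23), and 3 adjusted over the list alone (camera adjusted p = 0.00741, and adjusted p = 0.486 with an estimated correlation). The 25 Wnt beta-catenin targets did not move as a group (camera adjusted p = 0.894), with 4 higher and 4 lower, 7 and 4 adjusted over the list alone, CDX2 and the receptor FZD7 (0.46) among the former and DKK1, DKK4 and T among the latter. The 32 pluripotency genes likewise had 4 higher and 4 lower, 9 and 5 adjusted over the list alone (camera adjusted p = 0.391), with SOX2 higher and GDF3 lower. The remaining lists had camera adjusted p from 0.119 to 0.911.

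**Figure D3:**
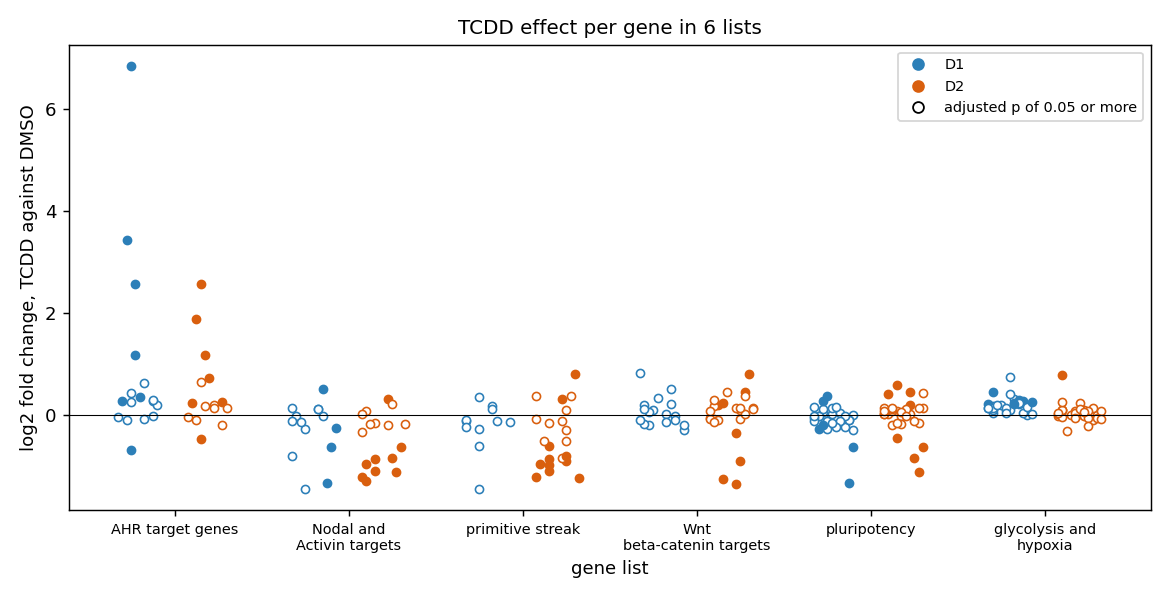
Log2 fold change of TCDD against DMSO (vertical axis) for each member of 6 gene lists (horizontal axis) at D1 and D2, filled where the edgeR adjusted p was under 0.05. Members whose DMSO and TCDD means summed to under 1 CPM at a time are left out there. At D2, 8 of 17 Nodal and Activin targets and 9 of 23 primitive streak genes were called lower.

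Of the 52 D2 calls named by the rule, 33 held in all 8 fits that left out a library. CYP1A1 lost its call without replicate 1 or 2 of DMSO at D2 or replicate 1 of TCDD at D2 (edgeR adjusted p = 0.0976 to 0.213), and APELA without any of the 4 D2 libraries (0.0987 to 0.2). GATA4 and GATA6 lost it without DMSO replicate 2 or TCDD replicate 1 of D2 (0.0548 to 0.12 and 0.11 to 0.167), APLNR and FOS without DMSO replicate 1 or TCDD replicate 2 (0.32 to 0.466 and 0.269 to 0.274), RIT2 without replicate 2 of DMSO or TCDD (0.144 to 0.224) and ZDHHC8P1 without TCDD replicate 2 (0.092). BAMBI, ID4 and JAG1 lost it without either DMSO library or TCDD replicate 1 of D2 (0.139 to 0.299, 0.0562 to 0.102 and 0.123 to 0.273), ITGB4 without either DMSO library or TCDD replicate 2 (0.0675 to 0.235), PHLDA1 without replicate 1 of DMSO or TCDD (0.104 to 0.173), and BMP4, KRT8 and KRT19 in 5 of the 8 fits (0.0552 to 0.356, 0.0515 to 0.493 and 0.058 to 0.487). The count fell from 500 to 215, 268 and 248 without DMSO replicate 1, DMSO replicate 2 and TCDD replicate 2 of D2.

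In D2 against D1 with DMSO, called differentiation here, streak genes rose from near silence. Time in culture, the medium with its GSK3 inhibitor and any batch between the times cannot be told apart in this comparison. EOMES rose from 0.152 ± 0.000267 to 191 ± 7.44 CPM (SD, n = 2 each), a log2 fold change of 10.26 (edgeR adjusted p = 4.72e-23). The SE that the F statistic gives for EOMES, 0.13, understates the error of a ratio against so few counts at D1. The Wnt target SP5 rose from 0.14 ± 0.0541 to 200 ± 9.6 CPM, T from 0.0889 ± 0.054 to 90.5 ± 3.12 CPM, MIXL1 205-fold to 297 ± 15.9 CPM, and GAD1, glutamate decarboxylase, 183-fold to 117 ± 4.1 CPM. Several genes had no count in the DMSO libraries at D1 and were higher at D2 by at least 293-fold (EVX1), 119-fold (WNT8A), 88.2-fold (DKK4) and 86.9-fold (HOTAIRM1) against a floor of 3 counts over the group. FOXA2, an endoderm factor with 3 counts at D1, was higher by a ratio of 141 (95% counting interval 47.8 to 685). Among pluripotency genes, NANOG rose (log2 fold change 0.65), SOX2 fell (-0.48) and POU5F1 was at 470 ± 6.38 against 451 ± 5.42 CPM (edgeR adjusted p = 0.267). AHR fell (-0.44) and ARNT had a log2 change of 0.00 ± 0.05 (edgeR adjusted p = 0.000663 and 0.997).

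Between D1 and D2 with DMSO, 10912 of 17268 genes changed, 5613 higher and 5299 lower, of which 691 and 1646 by at least 2-fold. With no composition scaling, the split was 4377 higher and 6425 lower. The largest falls were NPTX1 (log2 fold change -5.64), a neuronal pentraxin, MYH2 (-4.32), GALNT9 (-4.32), TLE6 (-3.81), SGMS2 (-3.57), TMEM130 (-3.55), KLHDC8A (-3.48), GABRP (-3.41), RIPOR3 (-3.41) and the neurotrophin receptor NGFR (-3.37). Of 36 lists, 13 passed camera, 9 in the upward and 4 in the downward direction, and 2 passed with an estimated correlation. Of 23 primitive streak genes, 20 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 9.15e-61, and adjusted p = 0.0126 with an estimated correlation). All 17 Nodal and Activin targets changed, 12 higher and 5 lower, also over the list alone (camera adjusted p = 3.23e-26, and adjusted p = 0.0418 with an estimated correlation), with NODAL up 20-fold to 291 ± 16.7 CPM. Of 25 Wnt beta-catenin targets, 20 rose and 3 fell, also over the list alone (camera adjusted p = 1.11e-33, and adjusted p = 0.0731 with an estimated correlation).

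The other 10 lists that passed in differentiation lost the call with an estimated correlation. Of 30 glycolysis and hypoxia genes, 24 rose and 3 fell, also over the list alone (camera adjusted p = 8.46e-11, and adjusted p = 0.495 with an estimated correlation), with PDK1, a kinase that inhibits pyruvate dehydrogenase, up 8.14-fold to 653 ± 6.73 CPM. Of 29 S phase genes 23 rose, 24 over the list alone (camera adjusted p = 0.000636, and adjusted p = 0.519 with an estimated correlation), for example the flap endonuclease FEN1 (0.71). Of 29 oxidative phosphorylation genes 23 rose, 26 over the list alone (camera adjusted p = 0.00238, and adjusted p = 0.495 with an estimated correlation), for example cytochrome c, CYCS (0.73). Of 32 cytosolic ribosomal protein genes 30 rose, also over the list alone (camera adjusted p = 0.00177, and adjusted p = 0.502 with an estimated correlation). Of 25 cholesterol biosynthesis genes 1 rose and 19 fell, also over the list alone (camera adjusted p = 0.00177, and adjusted p = 0.519 with an estimated correlation), for example squalene synthase, FDFT1 (-1.01). Of 29 Wnt ligands and receptors 11 rose and 9 fell, also over the list alone (camera adjusted p = 0.00177, and adjusted p = 0.495 with an estimated correlation), with FZD10 at 3.01. Of 14 endoderm genes 8 rose and 3 fell, also over the list alone (camera adjusted p = 0.00222, and adjusted p = 0.495 with an estimated correlation), with GSC at 5.19 and HHEX at 3.25. Of 24 epithelial genes 3 rose and 15 fell, also over the list alone (camera adjusted p = 0.0256, and adjusted p = 0.502 with an estimated correlation), with CLDN4 lower (-1.56) and CDH1, E-cadherin, higher (0.74). Of 13 neural crest genes 2 rose and 5 fell, also over the list alone (camera adjusted p = 0.0112, and adjusted p = 0.327 with an estimated correlation), with FOXD3 at -3.24. Of 9 trophoblast and amnion genes 1 rose and 6 fell, also over the list alone (camera adjusted p = 0.0256, and adjusted p = 0.384 with an estimated correlation), with KRT7 at -3.35, a list call lost without DMSO replicate 1 of D2 (camera adjusted p = 0.0512). The remaining 23 lists had camera adjusted p from 0.123 to 0.934. ACTB was lower (-0.34) and GAPDH higher (0.32) at D2.

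With TCDD, the same time comparison changed 11271 genes, 5710 higher and 5561 lower, of which 661 and 1819 by at least 2-fold. With no composition scaling, the split was 4183 higher and 6992 lower. EOMES reached 106 ± 6.93 CPM from 0.146 ± 0.0901 CPM and MIXL1 128 ± 12.5 CPM from 1.35 ± 0.193 CPM. CYP1A1 fell from 89.4 ± 16.5 to 2.19 ± 0.529 CPM (log2 fold change -5.34 ± 0.18, edgeR adjusted p = 1.43e-08), TIPARP from 63.7 ± 2.53 to 33 ± 0.477 CPM (-0.95) and AHRR from 3.54 ± 0.252 to 1.35 ± 0.122 CPM (-1.40), while AHR had a log2 change of -0.06 ± 0.10 (edgeR adjusted p = 0.646).

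The D1 and D2 responses to TCDD, which share no library, overlapped. Of 127 genes higher at D1 and 241 at D2, 50 were shared, with 1.77 expected for independent lists (one-sided Fisher exact p = 2.29e-60), among them LRAT, TIPARP, CYP1B1, PCDH8, LHX4 and MYADML2. Of 70 genes lower at D1 and 259 at D2, 16 were shared, with 1.05 expected (one-sided Fisher exact p = 4.97e-15), among them LEFTY1, LEFTY2, ID1, GRPR, BMP4 and the N-cadherin gene CDH2. A further 7 genes were called at both times with opposite signs, including GAL, PRDM14 and CYP26A1. The Fisher test treats genes as independent and equally likely to be called. Whether D1 and D2 cells came from the same exposed cultures is not given, so a difference between cultures could also recur at both times.

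The size of the TCDD effect differed between the times for 142 genes, with 91 having a more positive and 51 a more negative effect at D2. With no composition scaling, the split was 75 and 65. The effect was smaller at D2 for LRAT, by 2.20 ± 0.10 on the log2 scale, a difference of -2.20 (edgeR adjusted p = 3.02e-10), TIPARP (-1.55), CYP1B1 (-1.41) and DNAH5 (-1.36), and GMPR, which fell at D2, had a difference of -1.14. More positive effects at D2 were led by S1PR1 (1.22), a sphingosine phosphate receptor, PCDH18 (1.08), the serotonin receptor HTR1D (1.03), MICAL2 (1.03) and PROX1 (1.01), and SOX2 had a difference of 0.75 ± 0.07 (edgeR adjusted p = 2.38e-06). The difference for CYP1A1, -4.27 ± 0.77, did not pass (edgeR adjusted p = 0.0596). The adjusted p ran from 1.47e-25 to 0.447 over its alternatives and passed in 8 of 16, and only 9 of the 21 differences called among named genes held in all 8 fits that left out a library. Of 36 lists, 6 passed camera for the difference, 1 in the upward and 5 in the downward direction, and 0 with an estimated correlation or with fry. The count was 53, 82, 49, 80, 269 and 63 without DMSO replicate 1 or 2 of D1, DMSO replicate 1 or 2 of D2, TCDD replicate 1 of D1 and TCDD replicate 2 of D2.

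Of 259 genes lower with TCDD at D2, 163 rose and 44 fell in differentiation with DMSO, and of 241 higher genes 88 rose and 108 fell. Both comparisons contain the DMSO libraries of D2, which favours such a split, and its size without a TCDD effect was not computed. Across the 10912 genes called in differentiation, which are not independent replicates, the TCDD effect at D2 and the differentiation effect had a Pearson r of -0.179 and a covariance of -0.0385. Simulations with no TCDD effect, which carry the shared DMSO libraries, gave a mean r of -0.088 (-0.125 to -0.049) and a covariance of -0.0139. Versions that shared no library gave r of -0.096 and -0.118 (covariances -0.0251 and -0.0309). No simulation was run for these versions, so the simulated range does not apply to them. The share of genes with the same sign in both effects was 49.8%, equal to the simulated mean of 49.8%, and 48.7% and 50% in the versions that shared no library.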

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

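The tests of explanations in this part were chosen after the results they address were seen, on the same data. The edgeR tests, the list tests and the fits that left out a library had been fixed before. The comparison of TCDD effects between the times gave 142 genes and 6 lists, and the results reported for its named genes and lists are given below as values.

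Streak and Nodal genes were lower with TCDD at D2, with a median log2 change of -0.946 over the 13 called-lower members of either list. The medians over all tested members were -0.502 for the streak list and -0.33 for the Nodal list. A smaller share of cells that had left the ESC state could lower every gene silent at D1 and induced at D2 by a common factor. The 11 such members of either list, chosen by their levels with DMSO, differed by more than their error (5 lower, 1 higher, Cochran's Q per degree of freedom 36.3, against 1 for error alone), as did all 43 such genes (16 lower, 3 higher, 24 not past the test, 20.6), which speaks against a common factor as the whole cause. The error here is the spread between libraries, which may be technical. The DMSO libraries of D2 entered both the choice of genes and their TCDD effect. GC content or transcript length bias between libraries might also have shifted the called-lower members, but their median was -0.959 after a loess correction for both. A delay in differentiation was not tested and stays open, as does any effect of culture or plating that differed between the DMSO and TCDD libraries.

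The TCDD effect was less positive at D2 than at D1 for 16 genes raised at D1, of which 7 had more and 9, such as GAL and CYP26A1, less CPM with TCDD than with DMSO at D2. Less AHR RNA might explain a smaller rise, but the log2 change of AHR between the times with TCDD was -0.055 ± 0.1 (edgeR adjusted p = 0.646). A higher untreated level at D2 could shrink a fold change, and it rose for 10 of the genes. The log2 change at D2 lay below that expected from the CPM added at D1 by more than the 95% error for 8 of them, including LRAT (-1.56), TIPARP (-1.02) and CYP1B1 (-0.61), but not for PDK1 (-0.14) and EGLN1 (-0.14), with a median difference of -0.48, so this stays undecided for the set. The genes had been chosen by a called rise at D1 and a called smaller effect at D2, which favours log2 changes below the expected ones. Loss of TCDD after the exposure, AHR protein and chromatin changes were not measured, so they stay open.

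The glycolysis and hypoxia list was higher with TCDD at D1 with the preset correlation (camera adjusted p = 5.31e-17), but not past the test with an estimated correlation (adjusted p = 0.486) or with fry (0.159). A single library standing apart could produce this, and the gap between the closest TCDD and DMSO library scores, 0.114, was smaller than the largest range within a group, 0.131. The call of the list glycolysis and hypoxia was kept in all 8 fits that left out a library (camera adjusted p = 9.68e-30 to 1.6e-07, the latter without TCDD replicate 1 of D1), so it did not need any single library, but with the preset correlation only, and spread between libraries stays open. GC content or transcript length bias may contribute little, as the list's median log2 change was 0.168 before and 0.139 after the correction. Oxygen, medium and cell density were not recorded in the sources used here and stay open.

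The other differences in TCDD effect (D2 minus D1, log2) were as follows. More negative effects were seen for LHX1 (-2.64), LRAT (-2.20), TIPARP (-1.55), CYP1B1 (-1.41), DNAH5 (-1.36), GMPR (-1.14), MIXL1 (-1.10), FGF4 (-1.09), GAL (-0.83), PDK1 (-0.38), BNIP3 (-0.36), P4HA1 (-0.33) and SPRED1 (-0.30). LHX1 was named through the streak list only, since its mean lay below the 1 CPM that the rule asks of the largest differences. More positive effects were seen for S1PR1 (1.22), PCDH18 (1.08), HTR1D (1.03), MICAL2 (1.03), PROX1 (1.01), SOX2 (0.75) and PRDM14 (0.69). MICAL2 lost its call without any of the 8 libraries (edgeR adjusted p = 0.0642 to 0.25), S1PR1 and SPRED1 in 7 of 8 fits (0.0581 to 0.236 and 0.071 to 0.221), and FGF4 in 6 (0.0605 to 0.219). GMPR, LHX1, P4HA1 and PDK1 lost it in 5 fits (0.0667 to 0.125, 0.0603 to 0.158, 0.0839 to 0.146 and 0.0521 to 0.13), PROX1 and MIXL1 in 4 (0.0808 to 0.167 and 0.0564 to 0.252), BNIP3 in 3 (0.0689 to 0.123) and DNAH5 in 2 (0.0564 to 0.0581).

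Of 18 AHR target genes, 0 rose and 2 fell in the difference, 1 and 4 adjusted over the list alone (camera adjusted p = 1.41e-06, and adjusted p = 0.316 with an estimated correlation). Of 30 glycolysis and hypoxia genes, 0 rose and 3 fell, 1 and 6 over the list alone (camera adjusted p = 2.46e-06, and adjusted p = 0.747 with an estimated correlation). Of 32 pluripotency genes, 5 rose and 2 fell, 9 and 3 over the list alone (camera adjusted p = 0.000531, and adjusted p = 0.734 with an estimated correlation). Of 19 immediate early genes, 0 passed, with 1 higher and 2 lower over the list alone (camera adjusted p = 0.0159, and adjusted p = 0.492 with an estimated correlation). Of 23 primitive streak genes, 0 rose and 3 fell, 1 and 4 over the list alone (camera adjusted p = 0.0199, and adjusted p = 0.734 with an estimated correlation). Of 23 FGF and ERK targets, 0 rose and 1 fell, 1 and 3 over the list alone (camera adjusted p = 0.0364, and adjusted p = 0.823 with an estimated correlation). With a library left out, the streak list lost its call without DMSO replicate 2 of D1, TCDD replicate 1 of D1 or TCDD replicate 1 of D2 (camera adjusted p = 0.0661 to 0.27), FGF and ERK targets in 4 of 8 fits (0.108 to 0.545) and immediate early genes without DMSO replicate 2 of D2 (0.0585). The other 30 lists had camera adjusted p from 0.101 to 0.896.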

How the results depend on the processing

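The replicate blocks within each time and with crossed numbers were added after the data were seen, and all other alternatives were fixed before. The count of 197 genes at D1 became 480 with no filter beyond 1 count, 29 with a further log2 threshold of 1, 78 to 246 over the fits that left out a library (78 without DMSO replicate 1 of D1) and 597 with a block within D1. The count of 500 at D2 became 885, 53 and 1143 with the same first, second and block alternatives, and 215 to 653 over the fits that left out a library, with 215, 268 and 248 without DMSO replicate 1, DMSO replicate 2 and TCDD replicate 2 of D2. The difference between the times moved from 142 to 433 with no filter, 15 with the log2 threshold and 49 to 269 over the fits that left out a library. D2 against D1 went from 10912 to 2337 with DMSO and from 11271 to 2480 with TCDD under the log2 threshold. Its counts were 9330 and 9734 with DESeq2, 9755 and 9979 with at least 1 CPM, and 9183 to 11286 and 9799 to 11300 with a library left out. A fit on only the groups compared gave 137 genes at D1 and 696 at D2, a wider gap than 197 and 500. The log2 threshold lowers every count by construction, and the cause of the other shifts was not tested.

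Without composition scaling, the share of higher genes went from 51.4% to 40.5% in D2 against D1 with DMSO, from 50.7% to 37.4% with TCDD and from 64.1% to 53.6% for the difference, and the median of all genes shifted by -0.086 and -0.109 in D2 against D1 with DMSO and with TCDD. RLE, DESeq2 and voom counts were 196, 169 and 190 at D1, 507, 364 and 465 at D2, and 145, 139 and 112 for the difference.

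Lists past camera numbered 7 at D1, 9 at D2, 13 in D2 against D1 with DMSO and 6 for the difference. With an estimated correlation they numbered 1, 3, 2 and 0, and with fry 1, 4, 25 and 0. For the difference, 5 to 12 lists passed with a library left out, 12 without TCDD replicate 2 of D1. At D1, lists lost their call without DMSO replicate 1 or TCDD replicate 1 of D1 for Nodal and Activin (camera adjusted p = 0.0565 to 0.272) and BMP and SMAD targets (0.0506 to 0.0565), without DMSO replicate 1 or TCDD replicate 2 of D1 for pluripotency (0.184 to 0.22), without DMSO replicate 2 or TCDD replicate 2 of D1 for amino acid stress (0.108 to 0.119), and without DMSO replicate 1 or TCDD replicate 1 of D1 or TCDD replicate 2 of D2 for paraxial mesoderm (0.0523 to 0.216). At D2, BMP and SMAD (0.259 to 0.276) and FGF and ERK targets (0.0759 to 0.167) lost it without DMSO replicate 2 or TCDD replicate 1, cardiac mesoderm (0.124) without TCDD replicate 1, and Notch (0.0794 to 0.0822) without DMSO replicate 1 or TCDD replicate 2.

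The sign changed in 34 of 5992 values of named genes, in 9 genes, none past the test in either fit. Without composition scaling, ARNT moved from -0.004 to 0.00 at D1, from 0.00 to -0.086 and from 0.04 to -0.07 in D2 against D1 with DMSO and with TCDD, and POU5F1 from -0.004 to 0.001 at D1 and from 0.06 to -0.026 with DMSO. ARNT with DMSO was -0.011 with DESeq2 and with RLE, -0.03 with at least 1 CPM, -0.007 with no filter and -0.015 with only the groups compared. Over the 8 fits that left out a library, the values at D1 ran from -0.038 to 0.025 for ARNT, -0.018 to 0.008 for POU5F1, -0.859 to 0.454 for EOMES (-0.008 with all libraries), -0.23 to 0.403 for GATA4 (0.053), -0.257 to 0.341 for ISL1 (0.097) and -0.255 to 0.038 for MIXL1 (-0.111). At D2 they ran from -0.078 to 0.261 for AHR (0.076) and -0.041 to 1.16 for ISL1 (0.641). In D2 against D1 they ran from -0.025 to 0.029 for ARNT with DMSO and -0.157 to 0.053 for AHR with TCDD (-0.055). For the difference they ran from -0.031 to 0.006 for ACTB (-0.011), -1.309 to 0.004 for EOMES (-0.847), -0.142 to 1.064 for ISL1 (0.545) and -0.891 to 0.685 for T (-0.12). The cause was not tested.

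The replicate number as a block gave 205, 502, 10887, 11226 and 145 genes at D1, at D2, in D2 against D1 with DMSO and with TCDD, and for the difference. Replicate differences correlated by 0.11 between DMSO and TCDD at D1, 0.047 at D2, 0.026 between the times with DMSO and -0.1 with TCDD. Over genes above a log2 CPM of 2 the values were 0.285, 0.185, 0.042 and -0.243. The numbers may thus share a source within each time, where a block raised the counts to 597 and 1143. Under it, named genes that had not passed did so at D1, SOX2 (edgeR adjusted p = 0.0133), PAX7 (0.0145), MMP2 (0.0236), AHR (0.0275), GAPDH (0.0327), SOX3 (0.0457) and CEBPB (0.0495), and at D2, DLL1 (0.00125), ETV5 (0.00226), HES1 (0.0122), DUSP4 (0.013), POU5F1 (0.0348) and IGFBP3 (0.0362). However, the labels give no pairing, and between the times the values with TCDD were negative. With numbers crossed between the times, D2 against D1 with TCDD gave 11712 genes.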

Other observations

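The gene groups of this part were chosen after their values were seen, as were its permutation and Fisher tests. The edgeR and list tests had been fixed before, and some of the genes were named by the rule. Each statement is a hypothesis from 2 libraries per group.

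The retinoic acid response list did not pass with TCDD (camera adjusted p = 0.543 at D1 and 0.801 at D2, with 1 of 17 members higher at D1 and 1 higher and 1 lower at D2). Of 3 retinoid enzyme genes picked by their values, with no list or test of such genes, LRAT rose at both times (log2 fold changes 4.77 ± 0.07 and 2.57 ± 0.07). CYP26A1 rose at D1 (0.54 ± 0.11, edgeR adjusted p = 0.0119, and 0.0627 to 0.103 without either DMSO library or TCDD replicate 1 of D1) and fell at D2 (-0.44 ± 0.10, edgeR adjusted p = 0.0133). DHRS3, which reduces retinal, had 0.09 ± 0.06 at D1 (edgeR adjusted p = 0.707) and rose at D2 (0.50 ± 0.08, edgeR adjusted p = 0.000519).

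Mesenchymal genes moved in both directions, and their list did not pass (camera adjusted p = 0.0978 at D1 and 0.431 at D2). CDH2, N-cadherin, fell at D1 (-0.45 ± 0.07) and D2 (-0.63 ± 0.06), VIM, vimentin, fell at D1 (-0.36 ± 0.06), MMP2, a matrix protease, fell at D2 (-0.24 ± 0.05), and COL1A1, collagen, rose at both times (0.20 ± 0.05 and 0.54 ± 0.05). Without DMSO replicate 1 of the same time, VIM (edgeR adjusted p = 0.0517) and MMP2 (0.102) lost their calls, and COL1A1 at D1 lost its call in 4 of 8 fits (0.0537 to 0.409). ZEB2, a repressor of E-cadherin, rose at D2 from 4.13 ± 1.05 to 8 ± 0.672 CPM. The 29 Wnt ligands and receptors did not pass at D2 (camera adjusted p = 0.894), with 4 higher and 2 lower, 5 and 4 adjusted over the list alone. The higher were WNT10B at 0.44 ± 0.10 and the receptors ROR1 at 0.63 ± 0.05 (and 0.39 ± 0.05 at D1), FZD7 at 0.46 ± 0.07 and FZD2 at 0.36 ± 0.07 (edgeR adjusted p = 0.0508 without DMSO replicate 1 of D2), and the lower were WNT3 (-0.97) and FZD5 (-0.32).

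TCDD may have affected Nodal targets more than Wnt targets at D2. Among genes that rose in differentiation, the mean log2 change was -0.644 over 12 Nodal and Activin targets and -0.02 over 20 Wnt targets, a difference of -0.624 (two-sided permutation p = 0.00462). The permutation treats genes as independent, although the estimated correlations were 0.119 and 0.217 within the lists at D2, and it restates the list results that prompted it. Of 13 protocadherins outside the gene clusters, 4 changed at D2, PCDH8 and PCDH18 higher and PCDH7 and PCDH10 lower, against 2.9% of all genes (one-sided Fisher exact p = 0.000403), and 1 changed at D1, against 1.14% (p = 0.139). The family was picked because members were seen among the D2 calls, so the D2 value restates that choice. Neighbouring genes may have responded together, since 14 adjacent pairs changed in the same direction at D1 against a permutation mean of 1.21, and 31 against 7.09 at D2 (one-sided permutation p = 1e-04 at both times, the smallest that 10000 permutations can give). Of these pairs, 1 and 3 overlap, so shared reads could add to the count. Some pairs share a gene, so an induced locus can count more than once. At D1 these included CYP1A1/CYP1A2 and CYP1A2/CSK, and SSR3/TIPARP-AS1, TIPARP-AS1/TIPARP and TIPARP/LINC00886. No biological explanation beyond these tests was examined, and whether these patterns recur in separate cultures stays open.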
